A study of Mus musculus with 6 samples.

How the data were processed

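The series measured gene expression in blood endothelial cells sorted from the mouse intestine. Per the labels, mice on a mixed C57BL/6 x 129 background received tamoxifen daily for 5 days, and the intestine was taken on day 6. In knockout mice, tamoxifen switches on a Cre recombinase that is driven by the villin promoter, which is active in intestinal epithelium, and so removes Apc, a negative regulator of Wnt signalling, from epithelial cells. The sample titles describe the control mice as WT with floxed Apc and name no Cre for them. The intestine was digested with collagenase, and endothelial cells were sorted by the surface marker CD31 after exclusion of cells with CD45, EpCAM or gp38, the last of which marks lymphatic endothelium and fibroblasts. RNA was amplified before labelling and was hybridised to Affymetrix Mouse Gene 2.0 ST arrays, 1 colour and 1 biological replicate per array, with 3 knockout and 3 control arrays.

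The deposited table holds log2 values per probe set for the 6 arrays. Per the submitters' processing notes these came from RMA in the oligo package, which corrects background, applies quantile normalization across arrays and summarises probes on the log2 scale. The versions were not given in the sources used here. The 41345 probe sets had medians between 4.77 and 4.81 on the 6 arrays. Arrays have no read depth, and the number of arrays limits the precision.

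Probe sets were named through the platform annotation, updated by gene identifier where symbols had changed. Of the probe sets, 23521 carried 1 gene symbol, 1814 several and 16010 none, and those with several or none were left out of the gene tests. For each of 22180 genes, the probe set with the highest mean over the 6 arrays was used. Genes were kept when this mean lay above the 90th percentile of 1429 olfactory, vomeronasal and taste receptor genes, a reference for background, which was a log2 value of 4.11. This left 15312 genes. Where a named gene's group mean lay below this level, its change is given as a lower limit, with each array of that group raised to the level where it was below it, or its group means are given instead. Among 32 changed genes with more than 1 probe set, 5 had probe sets of opposite sign.

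Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Adjusted p-values of genes come from this fit throughout. Log2 changes are knockout minus control, and ± after the log2 change of a gene is the standard error of this fit. After the change of a list mean, ± is the standard error from the spread of array means within groups, without shared variance. With the enterocyte mean as a covariate it is that of an ordinary linear model. Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over all lists with at least 5 genes above background. They were tested again with an estimated correlation and with fry. With an estimated correlation, camera also refers each list to the few residual degrees of freedom of the 6 arrays. A call lost there is thus not by itself evidence that correlation between genes removed it. There were 28 lists of endothelial and cellular programmes and 15 lists of cell type markers, the latter covering the cells that the sort could still hold. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

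Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 rises and the 10 falls with the largest fold among changed genes whose groups did not overlap, leaving out predicted genes, clones, microRNAs and other small RNAs, receptor genes and immune receptor segments. It also took up to 4 members of each programme list with the smallest p and every changed member where these numbered 6 or fewer, then the 3 brightest members and the 2 with the smallest p of each cell type list, and Apc and the sort markers. Genes named outside this rule are said to have been chosen after their values were seen.

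The procedure was tested on simulated data, with 200 changed genes among 15312 in each of 10 simulations of this comparison. It recovered 15.6% of genes changed by 0.5 on the log2 scale, 72.1% of those changed by 1, 95.2% of those changed by 2 and 98.6% of those changed by 3, and 4.42% of its calls were false. A list shifted by 0.3 was called in 10 of 10 simulations, and other lists in 5 of 410 tests. The simulated genes varied independently of each other, so these list figures do not cover correlated genes.

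Alternatives covered the background filter, the normalization, the choice of probe sets, the variance model, the threshold, array weights, a block for the replicate number and each array left out in turn. A sex covariate was not fitted, since all 6 arrays showed the same sex (Xist at background and Y-linked genes measured). Further settings were added after the data were seen, because enterocyte transcripts differed among the control arrays. In these, the knockout arrays were set against control 1 alone, or genes at least 1.5-fold higher in the mean of controls 2 and 3 than in control 1 were left out.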

Results

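Expression was measured on 6 arrays of blood endothelial cells sorted from the mouse intestine, 3 from mice with acute epithelial deletion of Apc and 3 from control mice. The single comparison asked how intestinal endothelium differs when the neighbouring epithelium has lost Apc. Correlations between arrays over the 15312 genes above background lay between 0.979 and 0.984 within the knockout group. They lay between 0.977 and 0.984 within the control group, and between 0.964 and 0.974 across groups. The first principal component held 43.0% of the variance and separated the groups, with control 1 the nearest of the controls to the knockout arrays.

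Apc itself changed by -0.16 ± 0.14 on the log2 scale (adjusted p = 0.65). It was deleted in epithelial cells and not in the sorted endothelium, so its level does not check the labels. Of the sort markers, Pecam1, which encodes CD31, was at 11.4 in both groups, and Ptprc, which encodes CD45, lay near background at 4.14 in the knockout and 4.46 in the control. Pdpn, which encodes gp38, was above background on all 6 arrays, with means of 5.11 and 5.42 (-0.30 ± 0.18, adjusted p = 0.461). Epcam was not above background (4.11) on the 3 knockout arrays, averaging 3.77, nor in control 1 at 3.88. Controls 2 and 3 were at 7.20 and 6.24. The difference between the groups did not pass (adjusted p = 0.172).

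Endothelial cells from knockout mice had higher Apln, the gene for the apelin peptide made by sprouting endothelial tip cells, which rose 5.69-fold (log2 change 2.51 ± 0.16, adjusted p = 0.000344). Adamts9, a matrix protease (3.19-fold), Timp1, a protease inhibitor (3.17-fold), and Plaur, the urokinase receptor (2.93-fold), rose as well, with adjusted p-values from 0.000344 to 0.00789. The tight junction gene Cldn5 fell 2.43-fold and the xenobiotic-metabolising Cyp1b1 3.49-fold. The largest falls that passed were in genes of intestinal epithelium, led by the antimicrobial lectin Reg3b (-4.64 ± 0.50, adjusted p = 0.00374) and by Spink1, a protease inhibitor, which fell from a mean of 9.33 to 5.33 (adjusted p = 0.0103).

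In all, 393 of 15312 genes passed an adjusted p of 0.05, with 168 higher and 225 lower in the knockout, and 129 of them changed at least 2-fold (40 higher, 89 lower). A group mean lay below background in 21 of the 393, and with the background level in its place 125 changed at least 2-fold. At an unadjusted p of 0.05 there were 2514 genes. The groups did not overlap for 22.0% of genes, against 10% by chance. The median change over all genes was -0.017 and the median standard error 0.15. Among the lower genes, 42 of 225 (18.7%) were at least 1.5-fold higher in controls 2 and 3 than in control 1, against 1 of 168 (0.595%) among the higher genes and 2.33% of all genes. The control values that define this class also enter the comparison, so part of this contrast is built in. The count of changed genes was 219 without knockout 1, 172 without knockout 2 and 91 without knockout 3. Without control 2 it was 194, and without control 3 it was 128. It was 139 without the variance trend and 52 against control 1 alone, a setting chosen after the data were seen, in which 40 of the 52 were among the 393.

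The other large rises were in Mt2, a metallothionein (3.32-fold), Bex1 (at least 2.55-fold, its controls not being above background), Slc7a5, an amino acid transporter (2.80-fold), Chrm2, a muscarinic acetylcholine receptor (2.80-fold), Inhbb, an activin subunit (2.78-fold), and Fkbp5, a glucocorticoid-inducible chaperone (2.68-fold). Their adjusted p-values ranged from 0.000344 for Chrm2 to 0.0367 for Mt2. Of the 10 largest falls that passed, 7 were on the enterocyte list, Spink1, Lypd8 and Guca2b not being members. The other log2 changes were -3.97 for Lypd8, -3.57 for Fabp1 and for Apoa1, -3.38 for Guca2b, -3.32 for Rbp2, -3.29 for Fabp2 and -3.14 for Krt20. Reg3g, not above background on 2 of the 3 knockout arrays, had a change of -3.30 or larger in size against the background level. Adjusted p-values lay between 0.00333 for Fabp1 and 0.0406 for Krt20.

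Tip-cell and angiogenic genes rose as a group. Of 34 measured members, 13 rose, 0 fell and 21 did not pass, and 22 passed when adjusted over the list alone (20 higher, 2 lower). Beside Apln, Plaur and Inhbb, the rises included Nid1, a basement membrane linker (0.88 ± 0.073, adjusted p = 0.00136), Igfbp3 (0.65 ± 0.059, adjusted p = 0.00189), the Tie2 ligand Angpt2 (0.79 ± 0.15, adjusted p = 0.0278) and Flt4, a VEGF receptor (0.65 ± 0.091, adjusted p = 0.0104). The VEGF receptor gene Kdr was at 0.28 ± 0.064 (adjusted p = 0.055) and the apelin receptor gene Aplnr at -0.57 ± 0.15 (adjusted p = 0.0966). The list had a median change of 0.34 and passed camera (adjusted p = 5.89e-12). The call held with an estimated correlation, adjusted p = 0.0456, and by fry, adjusted p = 0.000287. The mean of the list was 0.36 to 0.39 above the control mean on the knockout arrays and within -0.030 and 0.021 of it on the control arrays. Pan-endothelial genes had a median change of 0.032 and did not pass (adjusted p = 0.199). Among 28 members, Cldn5 was lower and Eng, a TGF-beta co-receptor, higher (0.26 ± 0.044, adjusted p = 0.0211). Of these members, 10 passed when adjusted over the list alone (7 higher, 3 lower). Mural transcripts (median -0.70) moved the opposite way to the tip-cell genes.

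**Figure D1:**
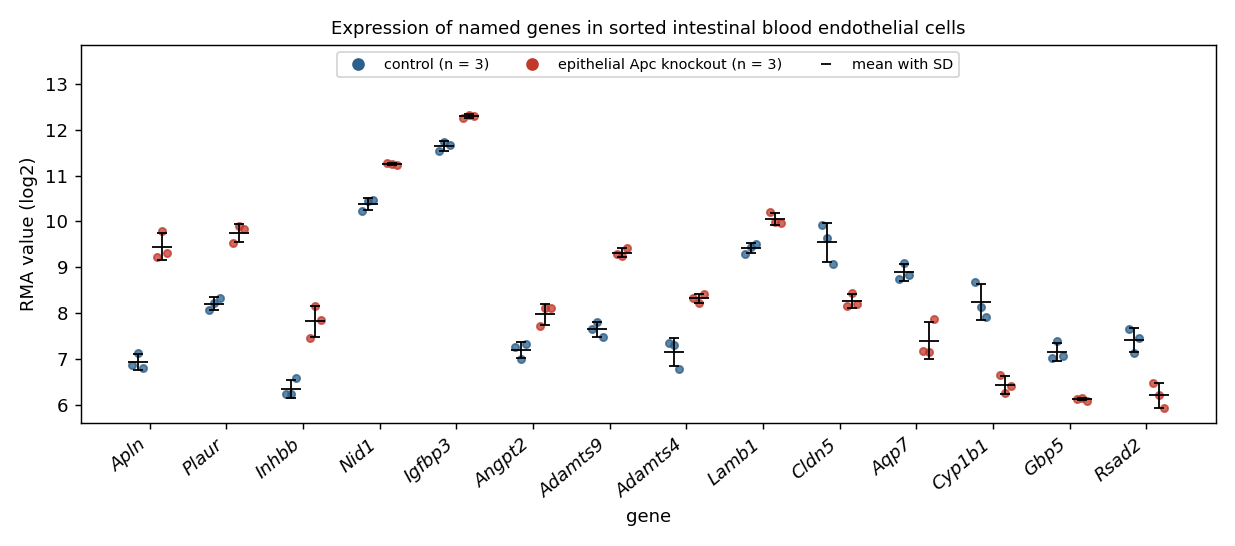
RMA values on the log2 scale (vertical axis) of 14 named genes (horizontal axis) on the 3 control arrays in blue and the 3 knockout arrays in red, with the mean and SD of each group in black. All of the genes plotted have groups that do not overlap, and Apln rises from a mean of 6.94 to 9.45.

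Basement membrane and matrix genes were the next group. Of 30 measured members, 7 rose and 0 fell, and 10 passed when adjusted over the list alone (9 higher, 1 lower). Adamts9 (1.67 ± 0.11, adjusted p = 0.000344), Adamts4 (1.17 ± 0.16, adjusted p = 0.00916) and the laminin chain gene Lamb1 (0.64 ± 0.091, adjusted p = 0.0113) were among the rises. The list passed camera (adjusted p = 1.95e-07), a call lost with the estimate (adjusted p = 0.362 with an estimated correlation). It shares 6 members with the tip-cell list, 4 of them called. The 24 members outside it, a subset chosen after the data were seen, gave a camera p of 0.000548 (p = 0.107 with an estimated correlation), with 3 of them called. Secreted factors of endothelium did not pass as a list (adjusted p = 0.757), but Sema3f, a guidance cue, rose 2.34-fold (adjusted p = 0.000344), while the chemokine gene Cxcl12 (-0.51 ± 0.089, adjusted p = 0.0237) and the macrophage growth factor gene Csf1 (-0.56 ± 0.12, adjusted p = 0.0482) fell. Of its 31 members, 8 passed when adjusted over the list alone.

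MYC and ribosome biogenesis genes leaned upward, 24 of 25 having a positive change and a median of 0.23. Only Srm, for spermidine synthase, passed on its own (0.79 ± 0.14, adjusted p = 0.0231), as the 1 call over the list alone too. The list passed camera (adjusted p = 1.73e-06; adjusted p = 0.472 with an estimated correlation). Cell cycle genes also passed as lists, with 0 genes called by limma and 3 members of each at an unadjusted p of 0.05. Knockout 3 lay level with control 2 for both, at 0.084 and 0.087 around the control mean for the G2/M list and 0.063 and 0.052 for the G1/S list. Knockouts 1 and 2 lay at 0.33 and 0.35 for G2/M and at 0.17 and 0.20 for G1/S. The G2/M list had an adjusted p of 0.00168 (adjusted p = 0.49 with an estimated correlation). Over the list alone 1 member passed, and Kif11 was at a mean of 4.74 in the knockout and not above background in the controls (adjusted p = 0.0636). The G1/S list had an adjusted p of 0.0144 (adjusted p = 0.37 with an estimated correlation), with 0 members past over the list alone and Mcm3 at 0.32 ± 0.12 (adjusted p = 0.223). Its estimated correlation was -0.0047, below the preset 0.01, so correlation between its genes does not explain the rise in p.

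STAT3 and acute-phase genes rose in 5 of 21 measured members, with 12 past when adjusted over the list alone (8 higher, 4 lower). They were Timp1, Saa3, a serum amyloid (1.12 ± 0.17, adjusted p = 0.013), Lrg1, an angiogenic glycoprotein (0.56 ± 0.10, adjusted p = 0.0227), the interleukin-4 receptor gene Il4ra (0.50 ± 0.087, adjusted p = 0.0237) and Serpina3n (0.86 ± 0.19, adjusted p = 0.0482). The list passed camera (adjusted p = 0.038; adjusted p = 0.588 with an estimated correlation). That call ended without knockout 3 (adjusted p = 0.111), without control 3 (adjusted p = 0.0522) and against control 1 alone (adjusted p = 0.24). Among 22 glucocorticoid receptor targets, Fkbp5 and Mt2 rose, 4 passed when adjusted over the list alone (3 higher, 1 lower), and the list passed camera (adjusted p = 0.00394; adjusted p = 0.588 with an estimated correlation). The knockout arrays lay at 0.087, 0.51 and 0.29 above the control mean. The call of the glucocorticoid list ended without knockout 2 (adjusted p = 0.0888) and against control 1 alone (adjusted p = 0.0853).

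Interferon-gamma and antigen-presentation genes fell in 7 of 29 measured members, with 0 rising and 12 past when adjusted over the list alone (1 higher, 11 lower). The falls included the guanylate-binding gene Gbp5 (-1.03 ± 0.14, adjusted p = 0.00878), the GTPase genes Igtp (-0.82 ± 0.11, adjusted p = 0.0104) and Irgm2 (-0.52 ± 0.10, adjusted p = 0.0281), and the immunoproteasome subunit gene Psmb9 (-0.41 ± 0.066, adjusted p = 0.0178). The list passed camera (adjusted p = 3.55e-07), and the call was lost with the estimate (adjusted p = 0.362 with an estimated correlation). Type I interferon genes passed as well (adjusted p = 0.000111; adjusted p = 0.588 with an estimated correlation), with 2 of 26 members lower and 8 past when adjusted over the list alone. They were Rsad2, an antiviral enzyme (-1.21 ± 0.18, adjusted p = 0.0137), and Cmpk2 (-0.94 ± 0.12, adjusted p = 0.00792). Markers of T and NK cells also passed as a lower list, with 0 genes called by limma and 5 at an unadjusted p of 0.05 (median -0.22, adjusted p = 0.00479; adjusted p = 0.588 with an estimated correlation). Over the list alone 3 passed, and Gzma, a granule protease, was at -1.87 ± 0.42 (adjusted p = 0.0536). The T and NK call ended without knockout 1 (adjusted p = 0.0553). The sort excluded CD45, which T and NK cells carry, and its gene Ptprc lay near background. Some other leukocyte genes did not. Gzma averaged 6.86 in the control and 4.99 in the knockout, the macrophage gene Cd68 7.92 and 7.98, and the B cell gene Ighm 10.6 and 11.2. The level of Ptprc thus does not show that leukocyte RNA was absent. Enterocyte transcripts (median -2.70) and mural transcripts (median -0.70) moved the same way as these lists. Against control 1 alone the type I list did not pass (adjusted p = 0.0621).

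Immediate early genes, which tissue digestion can induce, fell in 2 of 28 members, Jun (-0.39 ± 0.075, adjusted p = 0.0317) and Egr1 (-0.37 ± 0.076, adjusted p = 0.0406), with 10 past when adjusted over the list alone. The list passed camera (adjusted p = 1.50e-05; adjusted p = 0.695 with an estimated correlation). Control 1 lay 0.29 above the control mean for this list, while controls 2 and 3 lay at -0.20 and -0.085 and the knockout arrays between -0.28 and -0.20. The change of the list mean was -0.24 with all controls and -0.099 without control 1 (adjusted p = 0.00668). Between the groups, mural transcripts (median -0.70) and enterocyte transcripts (median -2.70) moved the same way as this list. Among the controls the enterocyte list ran the other way, with control 1 lowest at -1.12 and controls 2 and 3 at 0.76 and 0.35.

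Genes of capillary identity and lipid handling went both ways, and the list did not pass (adjusted p = 0.112). Of 24 members, 3 rose and 5 fell, and 17 passed when adjusted over the list alone (6 higher, 11 lower). The glycerol channel gene Aqp7 (-1.49 ± 0.19, adjusted p = 0.00792) and the triglyceride synthesis gene Dgat2 (-0.99 ± 0.14, adjusted p = 0.0113) fell, while the transcription factor gene Meox1 (0.95 ± 0.10, adjusted p = 0.00374) and the carbonic anhydrase gene Car4 (0.61 ± 0.10, adjusted p = 0.0178) rose. Junction and barrier genes also split, with 2 higher and 3 lower among 26 members (adjusted p = 0.298) and 11 past when adjusted over the list alone. Cldn5, the drug efflux pump gene Abcb1a (-0.53 ± 0.079, adjusted p = 0.0137) and the caveola gene Cavin2 (-0.51 ± 0.077, adjusted p = 0.0137) fell, and the gap junction gene Gja1 (0.73 ± 0.12, adjusted p = 0.019) and the glucose transporter gene Slc2a1 (0.48 ± 0.088, adjusted p = 0.0272) rose. Mural transcripts (median -0.70) and enterocyte transcripts (median -2.70) moved the same way as the lower genes of both lists. The Cldn5 call was lost without knockout 1 (adjusted p = 0.0509) and without knockout 3 (adjusted p = 0.0639).

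Wnt/beta-catenin targets did not pass as a list in the endothelium (adjusted p = 0.968). Of 21 measured members, 0 were called by limma, 6 had an unadjusted p under 0.05, 2 passed when adjusted over the list alone (1 higher, 1 lower), and Ccnd1 was at 0.51 ± 0.12 (adjusted p = 0.0546) and Sox17 at -0.52 ± 0.12 (adjusted p = 0.0644). Flow-responsive genes did not pass as a list (adjusted p = 0.298), but Cyp1b1 (-1.80 ± 0.19, adjusted p = 0.00378) and Cyp1a1 (-1.15 ± 0.22, adjusted p = 0.0337) fell, and 9 of its 21 members passed when adjusted over the list alone. Arterial, venous, inflammatory activation, hypoxia, BMP and TGF-beta, p53, oxidative stress and unfolded protein response lists did not pass (adjusted p from 0.198 to 0.968), and each held 1 to 3 called genes. Among these, Heyl, a Notch target (-0.86 ± 0.17, adjusted p = 0.0334), Steap4 (-1.04 ± 0.14, adjusted p = 0.00949) and the epoxide hydrolase gene Ephx1 (-1.18 ± 0.13, adjusted p = 0.00374) fell. Mural (median -0.70) and enterocyte transcripts (median -2.70) moved the same way as these falls and those of Cyp1b1 and Cyp1a1. Asns, for asparagine synthetase, rose 2.05-fold (adjusted p = 0.0137) and Skil, a TGF-beta signalling inhibitor, rose 1.67-fold (adjusted p = 0.0307). The YAP/TAZ, cholesterol synthesis, respiratory chain and ribosomal protein lists did not pass (adjusted p from 0.139 to 0.968), with 0 of 93 members called by limma and 17 at an unadjusted p of 0.05. Against control 1 alone, however, the arterial (adjusted p = 5.34e-06), inflammatory activation (adjusted p = 0.000348), flow (adjusted p = 0.0235), venous (adjusted p = 0.0295), ribosomal protein (adjusted p = 0.0402) and BMP and TGF-beta (adjusted p = 0.0482) lists passed as lower in the knockout. With an estimated correlation these 6 calls were lost in this setting, and so was that of the tip-cell list. The tip-cell list had an estimated correlation of -0.024 there, below the preset 0.01, so correlation did not cause its loss. The few degrees of freedom left by 3 knockout arrays and a lone control make this version of the test unable to decide. For all 6 lists, controls 2 and 3 lay below control 1, with differences from -0.34 for inflammatory activation to -0.078 for ribosomal proteins. The median, mean and set test differed in sign for the pan-endothelial, venous, Wnt target, hypoxia, unfolded protein, YAP/TAZ, respiratory chain, p53, oxidative stress, secreted factor and Cajal cell lists, which did not pass.

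**Figure D2:**
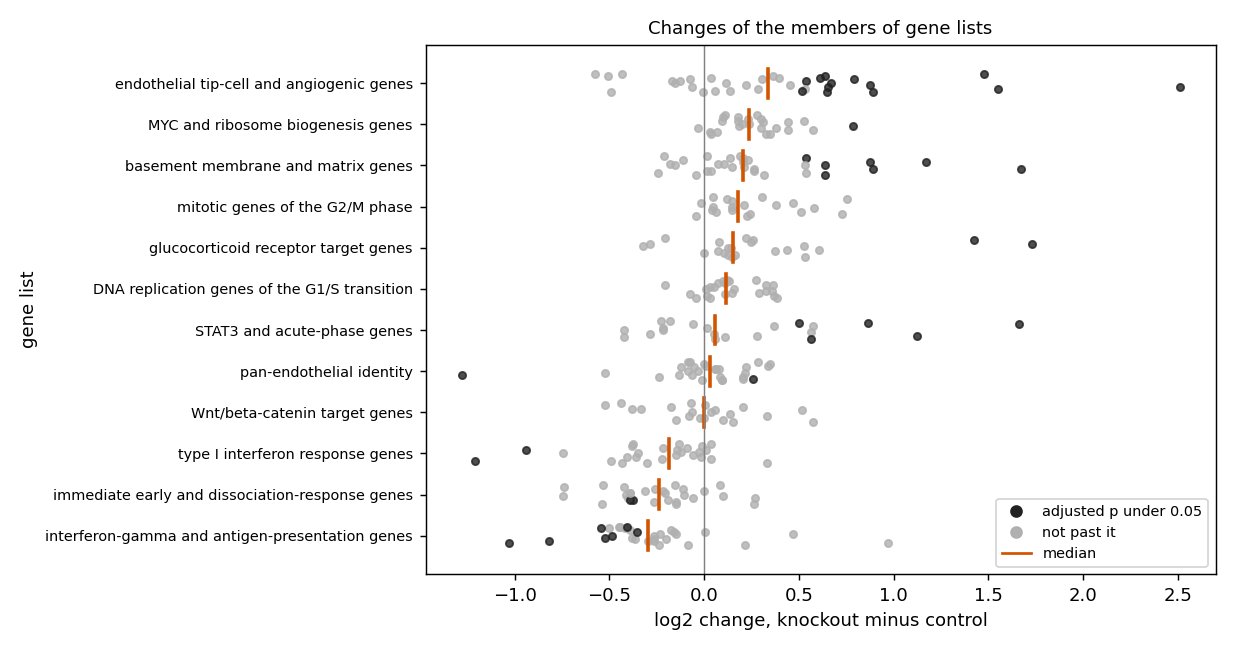
Log2 change, knockout minus control (horizontal axis), of each member above background of the 10 programme lists that passed camera, with the pan-endothelial and Wnt target lists for comparison (vertical axis). Black points passed an adjusted p of 0.05, grey points did not, and orange bars mark medians, from 0.34 for the tip-cell list to -0.29 for antigen presentation.

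In total 10 of 28 programme lists passed camera, 7 higher and 3 lower, and 1 of them, the tip-cell list, held with an estimated correlation. Another division of the 6 arrays, with knockout 1, knockout 3 and control 1 on one side, also gave 10 programme lists at the preset correlation. Such a mixed division keeps part of any real difference. The number of lists therefore cannot decide whether the real groups stand apart.

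Transcripts of other cell types differed between the groups, and 5 of 14 tested lists passed camera, all of them lower in the knockout, with 0 held by an estimated correlation. Enterocyte transcripts fell in 14 of 18 members, all 18 being past when adjusted over the list alone, with a median of -2.70, or -2.56 with groups below background set to that level (adjusted p = 5.68e-21; adjusted p = 0.399 with an estimated correlation). Their mean differed among the controls too, control 1 lying at -1.12 and controls 2 and 3 at 0.76 and 0.35 around the control mean, while the knockout arrays lay between -2.71 and -2.34. Crypt and pan-epithelial markers fell in 3 of 18 members, Phgr1 (-2.90 ± 0.48, adjusted p = 0.0193), Lgals4 (-2.14 ± 0.43, adjusted p = 0.0398) and Spint2 (-0.68 ± 0.14, adjusted p = 0.0401), with 10 past when adjusted over the list alone (list adjusted p = 1.95e-07; adjusted p = 0.399 with an estimated correlation). Control 1 lay apart here too, at -0.50, with controls 2 and 3 at 0.31 and 0.19. The median change was -0.58 with all controls and -0.27 against control 1 alone. Secretory epithelial markers, of goblet, Paneth, enteroendocrine and tuft cells, passed as a list, with 0 genes called by limma and 8 at an unadjusted p of 0.05 (adjusted p = 6.14e-05; adjusted p = 0.588 with an estimated correlation). Over the list alone 4 passed, with the Paneth defensin genes Defa24 at -1.40 ± 0.34 (adjusted p = 0.0671) and Defa22 at -0.33 ± 1.10 (adjusted p = 0.921). For this list control 1 lay at -1.31 around the control mean, level with the knockout arrays at -1.31, -0.93 and -1.09. The knockout was lower than controls 2 and 3 (0.53 and 0.78) and not than control 1. Against control 1 the mean change of the list was 0.20 and its median change -0.091. The sort excluded EpCAM-positive cells.

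Markers of mural cells, the pericytes and smooth muscle cells around vessels, fell in 6 of 17 members with a median of -0.70 (adjusted p = 8.04e-08; adjusted p = 0.399 with an estimated correlation), and 13 passed when adjusted over the list alone (1 higher, 12 lower). The falls included Des (-1.04 ± 0.12, adjusted p = 0.00451), Acta2 (-0.82 ± 0.15, adjusted p = 0.0291), Rgs5 (-0.70 ± 0.13, adjusted p = 0.0258) and Tagln (-0.70 ± 0.10, adjusted p = 0.0113). The sort took cells with CD31, which mural cells do not carry. Mural transcripts were measured all the same. The means of the list members ran from 6.02 to 11.68 in the control and from 5.48 to 10.98 in the knockout, the highest being Rgs5. The gate thus does not show that mural RNA was absent. Fibroblast markers did not pass (median -0.012, adjusted p = 0.884), but the collagen gene Col1a2 fell (-0.83 ± 0.17, adjusted p = 0.0433) and Cd34 rose (0.26 ± 0.054, adjusted p = 0.0468), with 3 past when adjusted over the list alone. Against control 1 alone the mean change of the list was -0.40 and its median change -0.36. Lymphatic endothelial markers did not pass as a list (adjusted p = 0.434), but Lyve1 (1.13 ± 0.23, adjusted p = 0.0406) and Flt4 rose, and 3 passed when adjusted over the list alone. The sort excluded gp38, and its gene Pdpn was measured on every array. The macrophage, neutrophil, B cell, glial, Cajal cell, blood cell and adipocyte lists did not pass (adjusted p from 0.107 to 0.884), with 0 of 73 members called by limma and 10 at an unadjusted p of 0.05. The mast cell list had 3 members above background and was not tested.

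**Figure D3:**
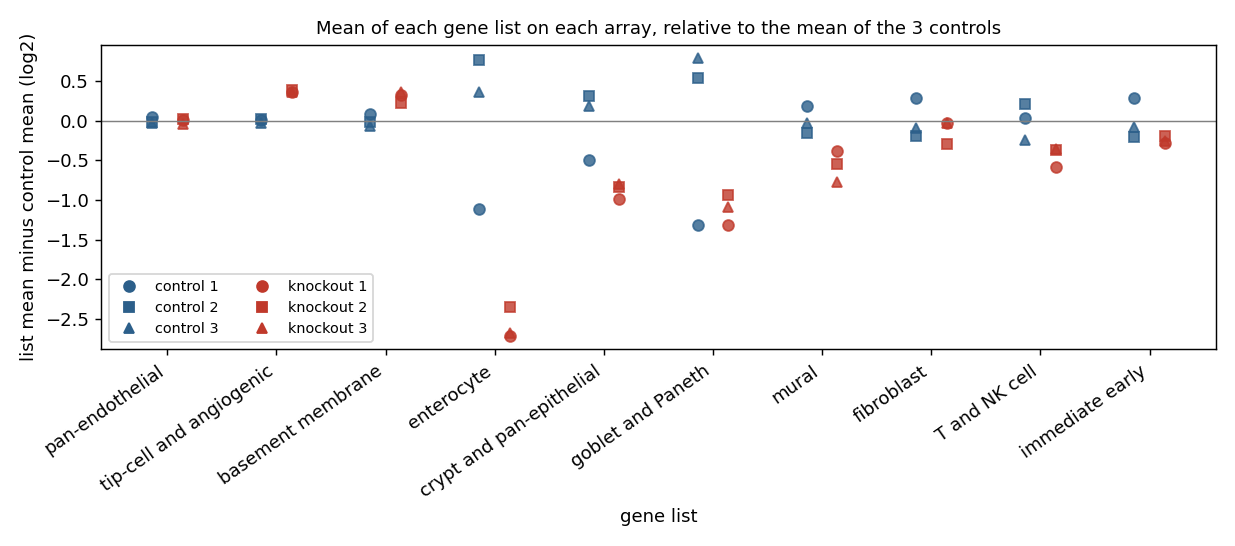
Mean of each gene list on each array minus the mean of the 3 controls, on the log2 scale (vertical axis), for 10 lists (horizontal axis), with controls in blue, knockouts in red and a symbol per replicate number. The tip-cell list lies at 0.36 to 0.39 on the knockout arrays, and the enterocyte list separates control 1, at -1.12, from controls 2 and 3. The list labelled goblet and Paneth also holds enteroendocrine and tuft cell markers.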

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

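The comparison against control 1 alone was chosen after the data were seen. So was the one without genes at least 1.5-fold higher in controls 2 and 3 than in control 1. The other settings were chosen before. All 393 changed genes kept their direction in every setting that measured them. Of these, 322 were measured under the stricter background and 350 without the genes higher in controls 2 and 3. Each probe set on its own was not compared gene by gene. The count of changed genes moved by over 1.5 times in these settings. It was 139 without the variance trend (58 higher, 81 lower), 5 with a t-test per gene that shares no variance between genes (2 higher, 3 lower), 768 at an adjusted p of 0.1 (323 higher, 445 lower) and 52 against control 1 alone (23 higher, 29 lower). Of the 5 genes from the t-test, 2 were among the 393 (2 higher, 0 lower). With each array left out in turn the count of changed genes ranged from 91 to 379. The higher genes ranged from 41 to 126 and the lower genes from 50 to 253. Fewer arrays and a lone control, assumed to vary like the other arrays, leave less power, and the cause of the trend effect was not tested. Without the genes higher in controls 2 and 3 there were 435 changed genes, but 3 cell type lists passed instead of 5. The enterocyte and secretory lists then had too few members for a test. The G1/S list lost its call under the stricter background (adjusted p = 0.156), as did the STAT3 list (adjusted p = 0.345), and the latter also with each probe set on its own (adjusted p = 0.066). The arterial list gained one without control 2 (adjusted p = 0.0164) and without control 3 (adjusted p = 0.0453), and the macrophage list without knockout 2 (adjusted p = 0.0124) and without control 3 (adjusted p = 0.027). The capillary list gained one in 3 settings (adjusted p from 0.0117 to 0.0498), with dim genes kept, with each probe set on its own and without control 1. The pan-endothelial list gained one after another quantile normalization (adjusted p = 0.0441), the ribosomal protein list under the stricter background (adjusted p = 0.0412) and the B cell list with each probe set on its own (adjusted p = 0.013). With an estimated correlation 1 programme list and 0 cell type lists passed, and with fry 1 and 0. Leaving out 1 array gave 9 to 11 programme lists and 4 to 6 cell type lists. Against control 1 alone 13 programme lists passed instead of 10. The arterial (adjusted p = 5.34e-06), inflammatory activation (adjusted p = 0.000348), flow (adjusted p = 0.0235), ribosomal protein (adjusted p = 0.0402), BMP and TGF-beta (adjusted p = 0.0482) and fibroblast (adjusted p = 0.0377) lists gained a call there. The type I interferon (adjusted p = 0.0621), STAT3 (adjusted p = 0.24) and glucocorticoid (adjusted p = 0.0853) lists lost theirs. With an estimated correlation the calls against control 1 alone were lost, that of the tip-cell list included. The few degrees of freedom there leave that version of the test unable to decide. In this setting the venous list turned lower (adjusted p = 0.0295), and the secretory list turned higher without passing (adjusted p = 0.731). The cause was not tested. Replicate numbers did not pair the arrays (correlations of deviations -0.021, -0.0074 and 0.039, with 1 of the 3 pairs closest to its own number), and the fit with the replicate number as a block called 394 genes, 310 of them among the 393 (130 higher, 180 lower). Over all settings, named genes kept direction and call 2971 times, lost a call 384 times, gained one 104 times and changed sign without a call 42 times. Individual lists kept both 800 times, lost a call 38 times, gained one 16 times and changed direction without a call 58 times. Direction changed with a call on either side 2 times, in the venous and secretory lists above. A sex covariate was not run, nor were the t-test, robust variance and fold threshold for lists, to which they do not apply. Genes near background, at 4.11, limit what can be seen, and a stricter background left 483 changed genes.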

Other observations

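The tests of epithelial makeup, mural share and tip-cell genes, and the gene lists for aryl hydrocarbon receptor targets and for amino acid genes, were chosen after the results were seen, and the other splits of the arrays were planned before. Of 26 amino acid genes above background, 5 passed, all among the 9 whose values had been seen, and all higher in the knockout. Slc7a5, a large neutral amino acid transporter, rose by 1.49 ± 0.28 and Asns by 1.03 ± 0.15. Slc1a5, a glutamine transporter (1.16 ± 0.16, adjusted p = 0.0113), Slc38a2, another amino acid transporter (0.45 ± 0.092, adjusted p = 0.0401), and the isoleucyl-tRNA synthetase gene Iars (0.55 ± 0.12, adjusted p = 0.0497) were picked after their values were seen. Of the 9, Chac1 (0.25 ± 0.19, adjusted p = 0.58), Trib3 (0.18 ± 0.22, adjusted p = 0.746), Sesn2 (0.12 ± 0.15, adjusted p = 0.758) and Ddit4 (0.38 ± 0.15, adjusted p = 0.262) did not pass. The stress genes Ddit3 (-0.41 ± 0.14, adjusted p = 0.18) and Atf3 (-0.54 ± 0.19, adjusted p = 0.202) did not pass.

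A broad amino acid response of the transcription factor ATF4 may underlie these 5 rises, and it was tested on 17 ATF4-linked amino acid genes whose values had not been looked at. Of these, 15 were positive with a median of 0.27, and 0 were called by limma. Camera gave p = 4.30e-06 at the preset correlation and p = 0.115 with an estimated correlation, and 5 of the 9 other splits of the arrays also gave the preset test a p under 0.05, the smallest being 1.21e-05. A preset p under 0.05 was the outcome written down beforehand as fitting the hypothesis, and it was met. It was set aside after the other splits were seen, since that test also passes for groups that mix knockout and control. Such mixed groups keep part of any real difference, so these splits cannot decide the question. Of the 9, 0 gave a p as small as the real groups, and the hypothesis stays open.

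Cyp1b1, Cyp1a1 and Ahrr, all targets of the aryl hydrocarbon receptor, which senses dietary and microbial ligands, fell together by 1.80, 1.15 and 0.84 on the log2 scale, Ahrr (adjusted p = 0.023) being picked after its value was seen. Lower receptor activity is a possible explanation. Mural (median -0.70) and enterocyte transcripts (median -2.70) fell too, and whether these 3 falls lie in the endothelium was not tested. Of the targets not yet looked at, Tiparp (-0.16 ± 0.16, adjusted p = 0.688) and Cyp1a2 (-0.011 ± 0.20, adjusted p = 0.986) were above background, and their median was -0.083 with 0 past limma's threshold, which leaves the hypothesis undecided, as does Nqo1 at -0.084 ± 0.14.

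Mir490, picked after its value was seen, was not above background on the control arrays and rose by at least 1.70 against the background level (adjusted p = 0.000344). In the RefSeq table of assembly GRCm38.p6 it lies inside Chrm2, which rose by 1.48 ± 0.099. Probe sets with several gene symbols or none were tested separately and 0 were called by limma, with 111 of 1185 and 927 of 8300 above background at an unadjusted p of 0.05.

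The rise of tip-cell genes could reflect a purer endothelial sort, or dilution of the controls by epithelial RNA. Both would raise pan-endothelial genes alike, but the tip-cell list rose by 0.40 ± 0.023 more than the 26 pan-endothelial genes outside it, which changed by -0.025 ± 0.031. That mean covers genes that moved both ways. Of the full list of 28, 15 were positive and 13 negative, with 7 higher and 3 lower past over the list alone. With the enterocyte mean of each array as a covariate, the tip-cell change was 0.37 ± 0.050 (95% interval 0.21 to 0.53), against 0.37 without it, and against control 1 alone it was 0.36. These values argue against both as the whole cause, and a response of the endothelium to the epithelial deletion stays as an untested hypothesis. The list had a camera p of 2.80e-13 for the real groups and at least 0.0114 in the 9 other splits, which all mix knockout and control arrays.

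The lower enterocyte transcripts could come from a smaller share of epithelial RNA of unchanged makeup. Among members well above background in the controls, 15 enterocyte genes changed by -2.82 ± 0.62 and 8 secretory genes by -1.21 ± 0.89, a difference of -1.61 ± 0.30, which a single common share would not give. The difference was -1.46 ± 0.22 over all members and -2.25 ± 0.42 for the 7 and 5 members well above background over all 6 arrays, a choice that the fall itself affects. It was -2.13 ± 0.31 against the 4 Paneth genes and -0.63 ± 0.61 against the 3 goblet genes, so the values do not argue against a common loss of enterocyte and goblet RNA. A different makeup of the epithelium in the knockout, or different expression within it, stays open, as does an amount of carried-over RNA that varies between arrays, since the enterocyte mean was 1.68 higher in controls 2 and 3 than in control 1.

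The lower mural transcripts may come from fewer mural cells in the sort. The gate for CD31 selects against such cells, but their transcripts were still measured, with Rgs5 at a mean of 11.68 in the control and 10.98 in the knockout. Of 17 markers, 14 were lower, around a weighted mean of -0.54, but their changes differed by more than their errors (heterogeneity statistic 135 on 16 degrees of freedom). Abcc9 at 0.49 ± 0.17, picked after its value was seen, was positive, which goes against an equal loss of every marker. Abcc9 did not pass over all genes (adjusted p = 0.179) but did over the mural list alone (adjusted p = 0.0221). Kcnj8 fell by as much (-0.53 ± 0.18, adjusted p = 0.0221 over the list alone). Synm and Smtn, at 0.14 and 0.16, were positive too and did not pass over the list alone (adjusted p = 0.495 and 0.168). The lower markers were not tested for a common fall on their own. Fewer mural cells and lower expression of some of their genes cannot be told apart here, since the markers are not all exclusive to mural cells.

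With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real groups gave 393 changed genes, 168 higher and 225 lower, in 1 of 10 splits, and the highest other split gave 1 gene. For lists, 2 of the 10 splits gave as many as the real one. The real groups gave 10 programme lists and the highest other split 10, and the real groups gave 5 cell type lists and the highest other split 6. In both cases the other split put control 1 with knockouts 1 and 3. The other splits all mix knockout and control arrays. A real difference between the groups is then partly kept in the contrast and partly counted as spread within groups. The counts of genes and lists in these splits thus cannot decide whether the real result is due to chance.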
